A study of Mus musculus with 32 samples.

How the data were processed

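Total RNA was sequenced from whole mouse placentas collected at 14.5 days post coitum. The 32 libraries came from 32 individual placentas, 4 for each of 8 genotypes. Per the labels' protocols, RNA was isolated with TRIzol, ribosomal RNA was depleted and strand-specific libraries were made with a TruSeq total RNA kit. The Nipbl series was on a mixed CD1 and C57BL/6 background and the Hdac8 series on C57BL/6, per the labels. The labels gave neither litter, embryo sex for the Nipbl series, dissection day nor sequencing batch, so p-values measure the spread between individual placentas and cannot separate placentas of different litters.

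The table deposited by the authors holds 1 log2 expression value per gene and library, already scaled between libraries. Per the submitters' processing notes, FastQC, STAR, HTSeq, DESeq2, DESeq and HOMER were used with the mm10 genome, with neither versions nor the role of each tool given. The values ran from -2.38 to 19.19, and the spread within groups was close to 0 for low genes. The median residual SD was 0.0032 for genes with a mean below 0, 0.098 for genes with a mean of 6 to 8 and 0.061 for genes with a mean above 10. Values of this form arise from a regularized log that shrinks low genes towards their mean over all libraries. Which transform was used is not given in the sources used here. Fold changes are therefore on a shrunken log2 scale and understate the change of low genes, including that of targeted genes at low levels. No counts were used, so the depth of each library is unknown, and neither a counting interval nor a detection floor can be given. The main analysis had been planned for log2(value + 1), but as the deposited values were already log2, no transformation was applied.

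Of 24557 entries, 2833 held 0 in every library and 5 repeated a gene symbol; these were left out, which kept 21720 genes. Genes were matched by gene identifier to the RefSeq annotation of GRCm38.p6, the assembly that mm10 denotes, and 33 genes had no chromosome there. Positions are on that build, are counted from 1 and span the whole gene. Whether a read came from an exon, an intron or an untranslated region cannot be told from a value per gene.

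Each model was fitted separately over its 16 libraries with limma 3.58.1 in R 4.3.3, with 1 mean per genotype, a trend of the variance with expression and robust moderation. Genes needed a linear value of at least 10 (log2 3.32) in at least 4 libraries of the fit. This left 14380 genes in the Nipbl series, 14384 in the Hdac8 series and 14414 in the fit over all libraries, which was used only to compare the models. P-values are two-sided with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. For targeted genes, exact permutation tests of the 4 against 4 values are two-sided and cannot give a p below 0.029. Comparisons were the mutant effect with PKR present and with PKR absent, PKR loss in mutants and in wild type, the interaction of both, and the difference between the 2 models' mutant effects. Comparisons between the mutant effects of both models, and between the mutant effects with and without PKR, share no libraries. Those within a model share its estimate of the spread.

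Genes were named by a rule. For the mutant effects with PKR present and for PKR loss in mutants, it took the 10 largest changes in each direction among genes that passed the threshold, had a mean log2 value of at least 5, had no overlap between the groups' libraries and had a symbol that is neither Gm with digits nor ends in Rik. Other comparisons took the 5 largest in each direction. Where fewer than 3 genes passed, the 3 smallest p-values in each direction were added and are said not to pass. Nipbl, Hdac8 and Eif2ak2 were always named, and so were up to 4 called members of each gene list, or the 2 with the smallest p where none passed. A gene that the rule takes is not reported here. Genes outside the rule are said to have been chosen after their values were seen. Members of the prolactin, Psg, cathepsin, globin, granzyme and protocadherin families have near-identical copies, so their reads can be split or shared and their values are uncertain. The same holds for Gm6548, which overlaps Eif2ak2.

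The 28 gene lists covered trophoblast (prolactin family, pregnancy-specific glycoproteins, placental cathepsins, spongiotrophoblast and glycogen trophoblast, labyrinth syncytiotrophoblast), other cells of the sample (fetal endothelium, erythroid cells, maternal decidua, natural killer cells, macrophages, neutrophils, yolk sac and visceral endoderm, mesenchyme and pericytes) and processes (p53 targets, DNA damage response and repair, senescence and secretory factors, interferon-stimulated genes, NF-kB targets, ATF4 and integrated stress response, unfolded protein response, cohesin and its regulators, clustered beta protocadherins, imprinted genes of the placenta, cell cycle, hypoxia response, angiogenic factors, nutrient transporters, immediate early genes). Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 28 lists of a comparison. Camera was repeated with an estimated correlation. With it, 0 lists passed in each of the 11 comparisons, and 0 to 5 lists had an unadjusted p under 0.05. Limma's fry tests whether the genes of a list move, on balance, one way; it does not compare the list with other genes. Fry was also run on genes called in other comparisons, adjusted over the 4 sets followed into the PKR-null groups and over both models for the signed interaction. Some counts of genes called for Nipbl heterozygosity without PKR are given as a percent of the genes tested.

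Mean log2 values of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty and of 13 yolk sac genes were computed per library. The tests, gene lists, naming rule and a first set of other settings were fixed before the data were examined. Those settings were a pseudocount of 8 added on the linear scale, no filter on low values, quantile normalization, a fit of only the groups compared, the replicate number as a block, each library left out in turn, an estimated correlation for the lists and, in the Nipbl series, the Y-linked mean as a covariate. Covariates for the yolk sac mean, for the Y-linked mean in the Hdac8 series and in the list tests, and fits without selected libraries were added after the data were seen. No library was left out of the main results.

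The gene test was run on data simulated with the real means and spread. With PKR present it recovered 44.8%, 77.6% and 97% of genes with true log2 changes of 0.2, 0.4 and 0.8 for Nipbl heterozygosity. For Hdac8 loss it was 46.3%, 89.6% and 97%. For the interactions it was 7.46%, 64.2% and 81.8% (Nipbl) and 20.9%, 64.2% and 97% (Hdac8). Each size had 66 or 67 genes, and 4 to 10 unchanged genes were called per comparison. Of 21 simulated lists of 20 genes (Nipbl, PKR present), camera called the shifted one (adjusted p = 1.28e-33) and 0 others. Other splits of the real libraries called up to 939 genes or 20 lists, so their structure is not covered.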

Results

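Gene expression was measured by total RNA sequencing in placentas of mouse models of Cornelia de Lange syndrome, a developmental disorder caused by mutations in cohesin and its regulators. NIPBL loads cohesin onto DNA, and HDAC8 deacetylates the cohesin subunit SMC3. The Nipbl series compared Nipbl heterozygous with wild-type placentas, and the Hdac8 series compared placentas with a mutant Hdac8 on the single X chromosome given in the labels with placentas carrying a wild-type copy. Each was studied with PKR present and in PKR-null animals. PKR, encoded by Eif2ak2, is a kinase that binds double-stranded RNA and phosphorylates the translation factor eIF2alpha. There were 8 groups of 4 individual placentas, collected at 14.5 days post coitum. Expression is given as the deposited log2 value. The depth of the libraries is unknown, because no counts were used. Over the 48 pairs of libraries within groups, Pearson's r across genes was 0.992 to 0.999 and the SD of the difference was 0.11 to 0.32 log2, so no library was a copy of another of its group.

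The targeted genes were examined first, as a check of the labels. Nipbl (gene identifier 71175, chromosome 15, 8289824 to 8465315, protein coding) was 11.55 ± 0.05 (SD, n = 4) in wild-type and 11.05 ± 0.04 in heterozygous placentas with PKR present, a fold of 0.704 (log2 difference -0.51 ± 0.03 SE, exact permutation p = 0.029). Without PKR the values were 11.5 ± 0.06 and 11.1 ± 0.06, a fold of 0.758 (-0.4 ± 0.04, exact permutation p = 0.029). Hdac8 (identifier 70315, chromosome X, 102284638 to 102505381, protein coding) was 7.04 ± 0.11 in wild-type and 6.75 ± 0.13 in mutant placentas with PKR present, a fold of 0.819 (-0.29 ± 0.08, exact permutation p = 0.029, limma adjusted p = 0.14). Without PKR it was 7.06 ± 0.14 and 6.59 ± 0.18, a fold of 0.725 (-0.46 ± 0.11, exact permutation p = 0.029, limma adjusted p = 0.055). In Nipbl wild type with PKR, where all 4 libraries were low in Y-linked genes, Ddx3y stood at 7.03 and Uty at 6.25. Values of this size therefore do not show whether Hdac8 RNA remained in the mutants, and the folds of such genes can be understated.

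Eif2ak2 (identifier 19106, chromosome 17, 78850504 to 78882572, protein coding) was lower in all PKR-null groups. Its fold was 0.62 in Nipbl heterozygous placentas (10.17 ± 0.07 against 9.48 ± 0.11, SD, n = 4), 0.633 in Nipbl wild type (10.1 ± 0.06 against 9.44 ± 0.05), 0.668 in Hdac8 mutants (10.11 ± 0.04 against 9.53 ± 0.06) and 0.699 in Hdac8 wild type (10.03 ± 0.08 against 9.52 ± 0.05). The exact permutation p was 0.029 in each, the smallest that 4 against 4 values can give. Each targeted gene was lower in all 4 of its mutant libraries than in all 4 libraries it was compared with. Eif2ak2 itself differed little between mutant and wild type of the same PKR genotype, by 0.08 and 0.05 log2 in the Nipbl series and 0.08 and 0.01 in the Hdac8 series with PKR present and absent, and passed the threshold in none of these 4 comparisons (limma adjusted p = 0.52, 0.78, 0.39 and 0.97).

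**Figure D1:**
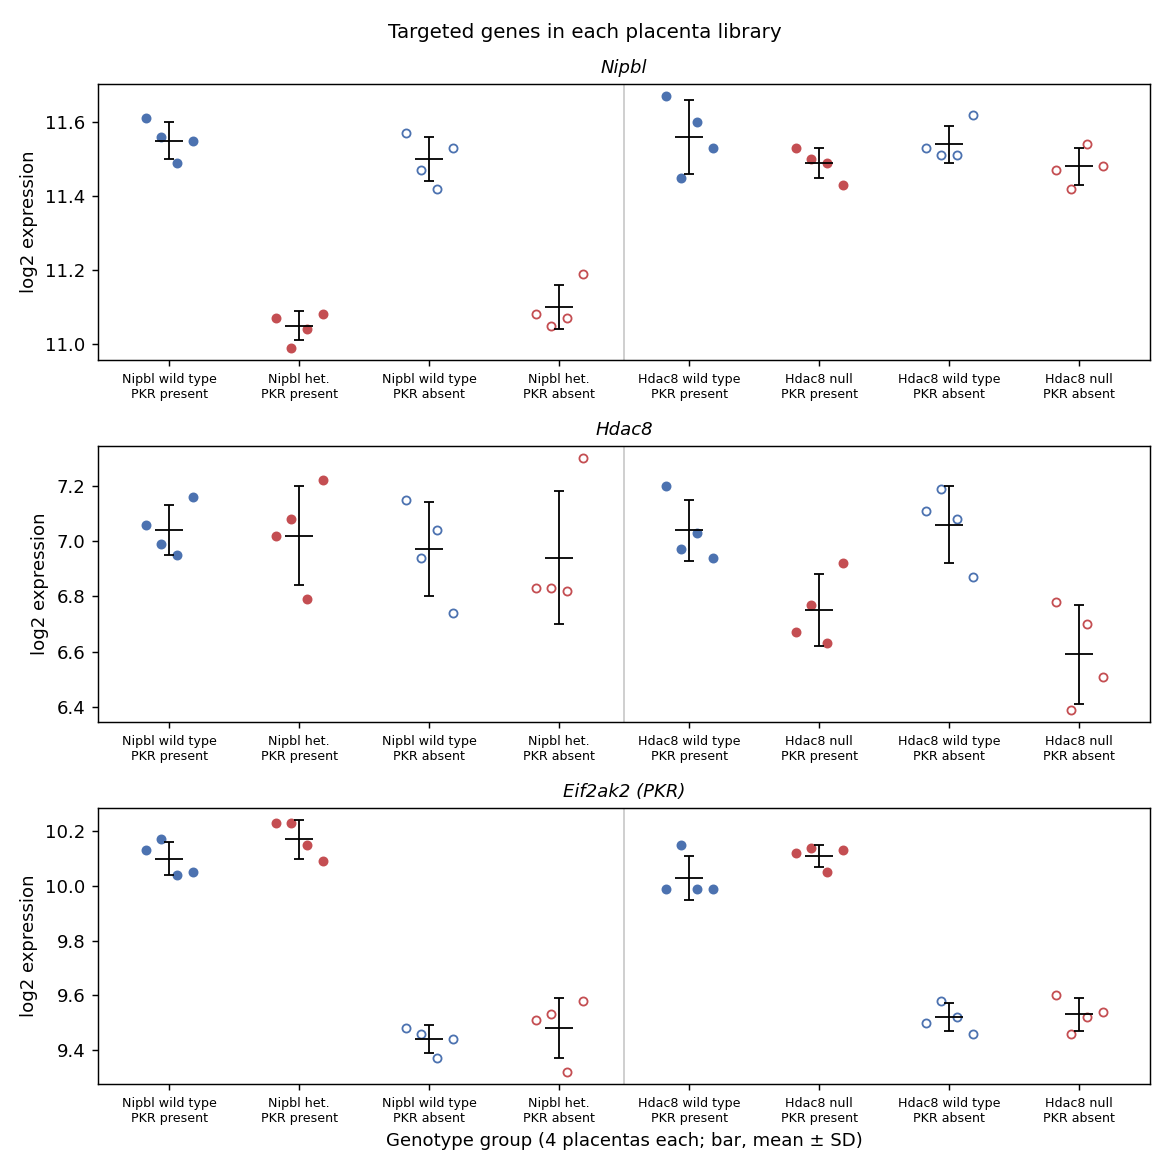
Deposited log2 values of Nipbl, Hdac8 and Eif2ak2 in each of the 32 placentas by genotype group, with group means and SD (n = 4 per group). Nipbl lies at 11.05 in heterozygous against 11.55 in wild-type placentas with PKR present, and Eif2ak2 lies between 9.44 and 9.53 on average in the PKR-null groups against 10.03 to 10.17 in the others.

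Y-linked and yolk sac transcripts separated libraries within and between groups. In 13 libraries the mean of Ddx3y, Eif2s3y, Kdm5d and Uty was 6.25 to 6.35 log2 with Xist, the RNA that coats the inactive X chromosome, at 13.14 to 13.8. In the other 19 the Y-linked mean was 8.58 to 9.4 with Xist at 10.65 to 12.01. Libraries low in Y-linked genes numbered 4 of 4 in Nipbl wild type and 3 of 4 in heterozygotes with PKR present, and 1 of 4 and 3 of 4 without PKR. In the Hdac8 series they were replicates 2 and 3 of the group labelled Hdac8 wild type without PKR, although its label gives a single X chromosome, and 0 in the other 3 groups. The mean of 13 yolk sac genes such as Afp, Alb and Ttr was 9.41 ± 0.58 (SD, n = 4) in Nipbl wild type and 8.57 ± 0.95 in heterozygotes with PKR present (exact permutation p = 0.2), and 9.06 ± 0.54 and 8.06 ± 0.41 without PKR (exact permutation p = 0.057). In the Hdac8 series it was 8.26 ± 1 in wild type and 8.74 ± 1.61 in mutants with PKR present (exact permutation p = 0.57), and 9.41 ± 1.24 and 8.72 ± 1.04 without PKR (exact permutation p = 0.4).

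**Figure D2:**
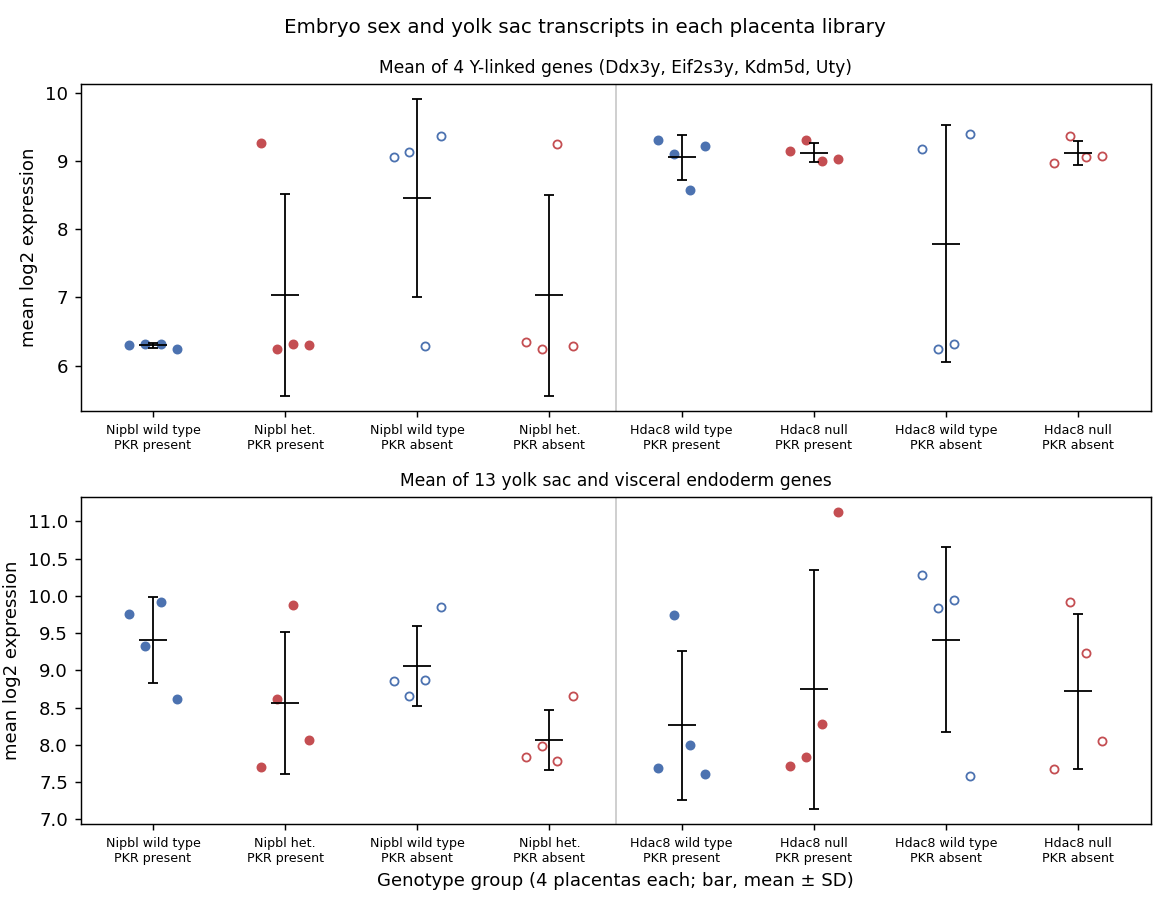
Mean log2 value of 4 Y-linked genes and of 13 yolk sac genes in each placenta by genotype group. The 13 libraries at 6.25 to 6.35 in the Y-linked mean lie apart from the 19 at 8.58 to 9.4, and the yolk sac mean spans 7.58 to 10.28 within the group labelled Hdac8 wild type without PKR.

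Nipbl heterozygosity with PKR present asked which placental transcripts change with partial loss of the cohesin loader. The transcripts that rose most included the chemokine Cxcl16 (chromosome 11, 70454389 to 70459984; 1.65-fold, log2 0.72 ± 0.11 SE, adjusted p = 0.0078, n = 4 per group), the sialyltransferase St8sia5 (1.54-fold, 0.62 ± 0.11), and the tight junction claudin Cldn4 (chromosome 5, 134945123 to 134946934; 1.48-fold, 0.57 ± 0.11). The epithelial transcription factor Grhl3 (1.46-fold, 0.55 ± 0.12), Lrrn4cl (1.45-fold, 0.54 ± 0.11) and the angiopoietin Angpt4 (1.42-fold, 0.5 ± 0.12) rose as well. Further increases were those of the sphingomyelinase Enpp7 (1.38-fold, 0.46 ± 0.09), the lipid-binding protein gene Sec14l2 (1.37-fold, 0.46 ± 0.07), the natriuretic peptide gene Nppb and the prostaglandin transporter gene Slco2a1 (both 1.35-fold, 0.43 ± 0.1 and 0.43 ± 0.08). The largest decrease was in Islr2, which encodes a membrane protein with leucine-rich repeats (chromosome 9, 58196297 to 58204319; fold 0.582, log2 -0.78 ± 0.09, adjusted p = 0.0013). Other transcripts that fell encode an ion pump regulator (Fxyd6, fold 0.608, -0.72 ± 0.17), a receptor of the LDL receptor family (Lrp3, 0.611, -0.71 ± 0.1) and the anion exchanger pendrin (Slc26a4, 0.634, -0.66 ± 0.15). An inhibitor of Wnt signalling (Apcdd1, 0.667, -0.58 ± 0.08), a caveolar protein (Cavin2, 0.676, -0.56 ± 0.13) and autotaxin (Enpp2, 0.685, -0.55 ± 0.12) fell. So did the carboxypeptidase Ace2 (0.688, -0.54 ± 0.11), a Ras exchange factor (Rasgrf2, 0.689, -0.54 ± 0.1) and a filamin-binding protein (Rflna, 0.691, -0.53 ± 0.11). In all, 213 of 14380 genes passed, 94 higher and 119 lower, Nipbl among them (adjusted p = 1.8e-05). Their median size was 0.26 log2 and the largest 0.78, and 10 of them lie on the sex chromosomes. The number fell to 69, 13, 18 or 87 without wild-type replicate 1, 2, 3 or 4 and to 19, 21 or 140 without heterozygous replicate 1, 2 or 3. With the yolk sac covariate it was 2. The fit behind the 19 held only libraries low in Y-linked genes (4 against 3). A fit of these groups alone called 324.

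Of the 28 gene lists, 11 passed camera in this comparison, 6 above and 5 below other genes. Of the interferon-stimulated genes, 32 of 33 were higher (median log2 fold change 0.14), with 0 called by limma over all genes and 2 higher when adjusted over the list alone. Rsad2 was at 0.34 ± 0.08 and Cxcl10 at 0.53 ± 0.13, neither past the threshold over all genes. The camera test had an adjusted p = 7.7e-06, and an adjusted p = 0.61 with an estimated correlation. Of the unfolded protein response genes, which serve protein folding in the endoplasmic reticulum, 14 of 15 were higher (median 0.17), 1 was called over all genes (Edem1, 0.22 ± 0.04) and 8 were higher when adjusted over the list alone. Set against other genes by camera, the list had an adjusted p = 7.4e-06, and an adjusted p = 0.61 with an estimated correlation. Pregnancy-specific glycoproteins, secreted by trophoblast, were higher in 20 of 22 (median 0.19; 0 called over all genes, 3 adjusted over the list alone). Their camera adjusted p = 8e-05, and the adjusted p = 0.61 with an estimated correlation. Among them were Psg29 at 0.31 ± 0.08 and Ceacam9 at 0.74 ± 0.2, both uncertain. Fetal endothelial genes were lower in 14 of 16 (median -0.12; 0 called over all genes and 3 adjusted over the list alone; Erg -0.21 ± 0.06, Sox17 -0.2 ± 0.06). Their camera adjusted p = 0.0041, and the adjusted p = 0.61 with an estimated correlation. Angiogenic factors were lower in 15 of 19 (median -0.1; 0 and 4 in the same order; Vegfa -0.36 ± 0.1, Dll4 -0.28 ± 0.08). For this list camera's adjusted p = 0.0084, and adjusted p = 0.61 with an estimated correlation. All 13 yolk sac genes were lower (median -0.91; Alb -1.29 ± 0.53, Cubn -1.04 ± 0.47; 0 called over all genes and 0 adjusted over the list alone). Their camera adjusted p = 0.00068, and the adjusted p = 0.61 with an estimated correlation. Also lower were 10 of 10 erythroid genes (median -0.21; camera adjusted p = 0.023) and 13 of 21 nutrient transporters (median -0.09; camera adjusted p = 0.028). Of these, the iron exporter gene Slc40a1 fell (-0.3 ± 0.07, adjusted p = 0.046). Macrophage genes (12 of 13 higher, median 0.14, camera adjusted p = 0.04), senescence and secretory factors (19 of 26, median 0.11, adjusted p = 0.026, Cxcl16 called, 5 higher and 1 lower adjusted over the list alone) and immediate early genes (12 of 17, median 0.09, adjusted p = 0.028) lay above other genes. With an estimated correlation, the adjusted p was 0.61 for the erythroid, nutrient transporter and senescence lists and 0.69 for macrophages and immediate early genes.

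The other 17 lists did not pass camera in this comparison. Single members were called in some. The p53 targets Mdm2, a ubiquitin ligase that acts on p53, rose (0.15 ± 0.03) and Plk2, a polo-like kinase, fell (-0.23 ± 0.05), with the list at adjusted p = 0.53. Nfkb2, a subunit of NF-kB, rose (0.25 ± 0.05; NF-kB targets, adjusted p = 0.26). In the hypoxia response (adjusted p = 0.7), the glycolysis regulator Pfkfb4 (0.34 ± 0.07) and the collagen prolyl hydroxylase P4ha2 (0.29 ± 0.07) rose and the pyruvate dehydrogenase kinase Pdk1 fell (-0.16 ± 0.03). The camera adjusted p was 0.27 for the prolactin family, 0.98 for placental cathepsins, 0.96 for spongiotrophoblast and glycogen trophoblast and 0.06 for labyrinth syncytiotrophoblast. For cells other than trophoblast it was 0.6 for maternal decidua, 0.96 for natural killer cells, 0.2 for neutrophils and 0.98 for mesenchyme and pericytes. It was 0.6 for DNA damage response and repair, 0.98 for ATF4 and integrated stress response and 0.53 for cohesin and its regulators. It was 0.41 for clustered beta protocadherins, 0.069 for imprinted genes and 0.097 for the cell cycle. No list passed with an estimated correlation in any of the 11 comparisons, and with fry 1 did, labyrinth syncytiotrophoblast for PKR loss in Nipbl heterozygotes. The yolk sac mean as a covariate ended the macrophage, senescence, immediate early and nutrient transporter calls (adjusted p = 0.18, 0.062, 0.11 and 0.11), and in each comparison that of the yolk sac list, whose own mean it is. The Y-linked covariate ended the nutrient transporter call (adjusted p = 0.066). The calls of the interferon, unfolded protein response, pregnancy-specific glycoprotein, endothelial and yolk sac lists held in 8 of 8 fits that left out 1 library. Those of the angiogenic list held in 7, of the erythroid, macrophage, senescence and immediate early lists in 5 and of the nutrient transporters in 4.

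Hdac8 loss with PKR present asked the same of loss of the SMC3 deacetylase. The transcripts that rose most encode integrin beta 6 (Itgb6, chromosome 2, 60598292 to 60722603; 1.47-fold, log2 0.55 ± 0.09 SE, adjusted p = 0.01, n = 4 per group), an alpha-tubulin (Tuba8, 1.41-fold, 0.5 ± 0.08) and a calcium pump of the secretory pathway (Atp2c2, 1.4-fold, 0.49 ± 0.07). Increases followed in a non-muscle myosin (Myh14, 1.38-fold, 0.46 ± 0.07) and a collagen-binding integrin (Itga11, 1.36-fold, 0.44 ± 0.1). Lgi2 (1.34-fold, 0.42 ± 0.07) and progranulin (Grn, 1.33-fold, 0.42 ± 0.05) rose, and, as in the Nipbl series, Nppb and Cldn4 (both 1.32-fold, 0.4 ± 0.08 and 0.4 ± 0.06). The ephrin receptor gene Epha4 fell most (chromosome 1, 77367182 to 77515107; fold 0.719, -0.48 ± 0.08, adjusted p = 0.013). It was followed by the transcription factor gene Nfib (0.724, -0.47 ± 0.1), Ankrd6 (0.733, -0.45 ± 0.06), Fxyd6 (0.741, -0.43 ± 0.1), Islr2 (0.747, -0.42 ± 0.08) and the imprinted zinc finger gene Zim1 (0.752, -0.41 ± 0.09). Smaller decreases were those of Cavin2 (0.756, -0.4 ± 0.09), the guidance ligand gene Slit2 (0.757, -0.4 ± 0.09), the neurotrophic factor receptor gene Gfra3 (0.764, -0.39 ± 0.09) and the cationic amino acid transporter gene Slc7a2 (0.766, -0.38 ± 0.07). In all, 157 of 14384 genes passed, 88 higher and 69 lower. Their median size was 0.23 log2 and the largest 0.55, and 6 of them lie on the sex chromosomes. Hdac8 itself did not pass (-0.29 log2, adjusted p = 0.14). The number was 38, 39, 85 or 38 without wild-type replicate 1, 2, 3 or 4 and 21, 62 or 35 without mutant replicate 1, 2 or 4. It was 14 in a fit of these groups alone, 92 without the filter on low values and 240 with the Y-linked mean as a covariate. All 8 placentas compared were high in Y-linked genes.

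The interferon-stimulated genes were again higher in 32 of 33 (median 0.12). Of these, 3 were called over all genes, the transcription factor Irf7 (0.28 ± 0.06), the RNA sensor Oas1a (0.21 ± 0.04) and Parp9 (0.18 ± 0.04), against 8 adjusted over the list alone. For this list camera's adjusted p = 1.6e-09, and adjusted p = 0.58 with an estimated correlation. Unfolded protein response genes were higher in 13 of 15 (median 0.11; limma called 0 over all genes and 7 adjusted over the list alone; Calr 0.16 ± 0.05, Sdf2l1 0.15 ± 0.05). Here camera gave an adjusted p = 0.001, against an adjusted p = 0.58 with an estimated correlation. Macrophage genes were higher in 12 of 13 (median 0.14; Adgre1 0.36 ± 0.09, Cd68 0.36 ± 0.1; 0 and 2 in the same order). Their camera adjusted p = 0.0039, and the adjusted p = 0.58 with an estimated correlation. Neutrophil genes were higher in 5 of 5 (median 0.18; 0 and 2). The camera test had an adjusted p = 0.024, and an adjusted p = 0.58 with an estimated correlation. Pregnancy-specific glycoproteins (20 of 22, median 0.13, camera adjusted p = 0.0012), senescence and secretory factors (18 of 26, median 0.1, adjusted p = 0.029) and immediate early genes (15 of 17, median 0.08, adjusted p = 0.033) lay above other genes. These 3 had an adjusted p = 0.64, 0.58 and 0.71 with an estimated correlation. Fetal endothelial genes were lower in 14 of 16 (median -0.1; Emcn -0.22 ± 0.06, Tek -0.26 ± 0.07; camera adjusted p = 0.004) and angiogenic factors in 14 of 19 (median -0.07, adjusted p = 0.024; the semaphorin and VEGF receptor gene Nrp1 fell, -0.32 ± 0.06). Imprinted genes were lower in 19 of 27 (median -0.07, adjusted p = 0.004, Zim1 called), erythroid genes in 8 of 10 (median -0.14, adjusted p = 0.024) and cohesin and its regulators in 13 of 15 (median -0.04, adjusted p = 0.024). These 5 lists each had an adjusted p = 0.58 with an estimated correlation. Of the yolk sac genes 13 of 13 were higher (median 0.52, camera adjusted p = 0.15). Mutant replicate 4 lay apart, at a yolk sac mean of 11.13 against 7.72 to 8.28 in the other 3 and at 19.8 against -5.9 to -3.1 on the first principal component (34.7% of the variance). Without it the list was lower (adjusted p = 0.42). Without wild-type replicate 2 or mutant replicate 1 or 2 it passed as higher (adjusted p = 0.0065, 0.026 and 0.035). In lists that did not pass, the prolactin-like hormone gene Prl7d1 rose (0.3 ± 0.07, uncertain), and the glycolytic enzyme gene Aldoc rose (0.25 ± 0.05). The matrix protein gene Postn (-0.27 ± 0.06) and the death receptor gene Fas (-0.18 ± 0.04) fell. Of the fits that left out 1 library, 8 of 8 held the calls of the interferon, unfolded protein response, endothelial and macrophage lists, 7 those of the pregnancy-specific glycoproteins, neutrophils and imprinted genes, and 4 to 6 those of the other 5.

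The mutant effects of both models were compared with PKR present to ask whether they share genes. Of the genes called, 37 were called in both models, 15 higher and 22 lower in both, against 1.1 in the same direction if lists of these sizes were independent. They include Cldn4, Nppb, Islr2, Fxyd6 and Cavin2 above. Others, chosen after their values were seen, were the scavenger receptor Colec12 (-0.49 and -0.37 log2 in Nipbl and Hdac8 mutants), Epha4 (-0.49 and -0.48), and the glucocorticoid receptor Nr3c1 (-0.28 and -0.28). In the same way the sodium pump subunit Atp1a2 (0.41 and 0.36), the kinase Plk3 (0.42 and 0.37), the oncostatin M receptor Osmr (0.28 and 0.31) and the antigen-loading chaperone Tapbp (0.22 and 0.19) rose. Of the 213 genes called in the Nipbl series, 204 had the same sign in the Hdac8 series, and of the 157 called there 153 had the same sign in the Nipbl series. Across 14361 genes the log2 fold changes correlated at Pearson's r = 0.46 and Spearman's rho = 0.51, where genes are not independent replicates. The difference between the mutant effects passed for 1 gene, Nipbl itself (-0.43 ± 0.06, adjusted p = 0.00081), and 468 genes had an unadjusted p under 0.05. Apcdd1 (-0.55 ± 0.11, adjusted p = 0.32), Ecm2 (-0.26 ± 0.06, adjusted p = 0.43), Pstpip1 (0.23 ± 0.05, adjusted p = 0.65), Clpp (0.16 ± 0.04, adjusted p = 0.72) and Fem1c (0.16 ± 0.04, adjusted p = 1) had the smallest p-values after it and did not pass. Of the lists, camera gave an adjusted p = 1.2e-05 for the yolk sac genes (13 of 13 lower in the Nipbl than in the Hdac8 comparison, median -1.36) and 0.038 for the unfolded protein response (14 of 15 higher, median 0.07), with an adjusted p = 0.91 with an estimated correlation for both. The yolk sac call held in 15 of 16 fits that left out 1 library and the unfolded protein response call in 8. The latter did not pass with the yolk sac covariate (adjusted p = 0.1) or with quantile normalization (adjusted p = 0.35). Without Nipbl wild-type replicate 1, 2, 3 or 4 the genes called in both numbered 14, 5, 6 or 17, and without heterozygous replicate 1, 2 or 3 they numbered 5, 7 or 24. Without Hdac8 wild-type replicate 1, 2 or 4 they numbered 17, 15 or 13, and without Hdac8 mutant replicate 1, 2 or 4 they numbered 10, 20 or 11. The difference called 2 genes without Hdac8 mutant replicate 4.

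**Figure D3:**
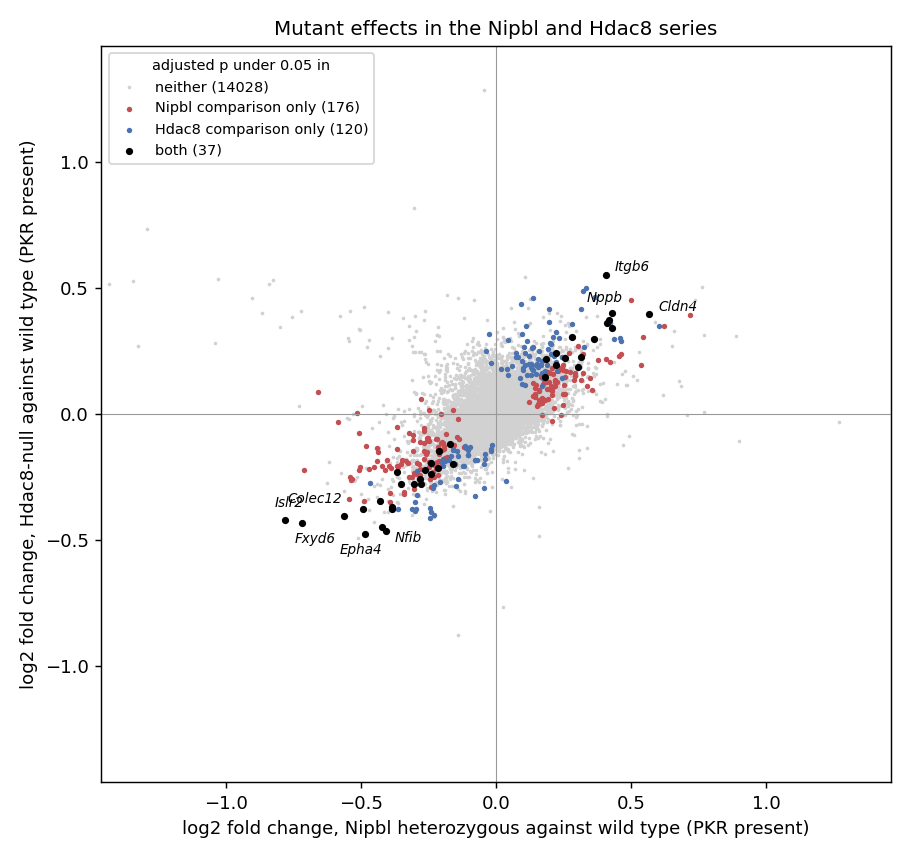
Log2 fold change of each gene in Nipbl heterozygous placentas (x axis) against that in Hdac8 mutant placentas (y axis), both with PKR present, with genes called in either or both models coloured. The 37 genes called in both lie in the same direction, and Pearson's r over 14361 genes is 0.46.

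Nipbl heterozygosity without PKR called fewer genes. The transcripts that fell most were Colec12 (chromosome 18, 9707648 to 9877995; fold 0.617, log2 -0.7 ± 0.09 SE, adjusted p = 0.0058, n = 4 per group), Islr2 (-0.54 ± 0.09, adjusted p = 0.024) and the cell adhesion gene Nrcam (-0.48 ± 0.07, adjusted p = 0.022). Next were the Wnt ligand gene Wnt7b (-0.45 ± 0.08, adjusted p = 0.03) and the sulfotransferase gene Chst8 (-0.45 ± 0.07, adjusted p = 0.022). The kinase gene Wnk3 (0.35 ± 0.06, adjusted p = 0.027), Reep4 (0.33 ± 0.06, adjusted p = 0.027), tissue plasminogen activator (Plat, 0.33 ± 0.06, adjusted p = 0.047), the succinyl-CoA ligase subunit gene Suclg2 (0.28 ± 0.05, adjusted p = 0.024) and Utp14b (0.27 ± 0.05, adjusted p = 0.045) rose. In all, 19 genes passed, 9 higher and 10 lower, Nipbl among them (adjusted p = 0.00049). Replicate 3 of the heterozygous PKR-null group lay apart from the other 15 libraries on the first principal component (23.3 against -13 to 7.9, 30.8% of the variance). Without it 0.786% of the genes tested passed, 85 higher and 28 lower, against 0.132% with it, and these included all 19. The number was 2, 4 or 4 without wild-type replicate 1, 2 or 3 and 7 or 8 without heterozygous replicate 1 or 2. It was 62 with the Y-linked mean as a covariate and 4 with the yolk sac mean. In a fit of these groups alone limma called 0 (1453 at an unadjusted p under 0.05). Interferon-stimulated genes were higher in 32 of 33 (median 0.15; Dhx58 0.39 ± 0.09; limma called 0 over all genes and 4 adjusted over the list alone). Set against other genes by camera, the list had an adjusted p = 1.1e-06, and an adjusted p = 0.76 with an estimated correlation. The yolk sac genes were lower in 13 of 13 (median -0.99; camera adjusted p = 3.9e-06), as were 10 of 10 erythroid genes (median -0.27, adjusted p = 0.0028) and 5 of 6 cathepsins (median -0.19, adjusted p = 0.0082, uncertain). Lower too were 12 of 14 decidual genes (median -0.3, adjusted p = 0.031), 14 of 16 endothelial genes (median -0.08, adjusted p = 0.045) and 14 of 21 prolactin genes (median -0.16, adjusted p = 0.045). Of the DNA damage response genes 20 of 24 were higher (median 0.06, adjusted p = 0.0057). Each of these 7 had an adjusted p = 0.76 with an estimated correlation. The unfolded protein response was at a median of -0.02 (camera adjusted p = 0.81). Of the libraries compared, 3 heterozygous and 1 wild-type were low in Y-linked genes. The interferon, yolk sac and erythroid calls held in 8 of 8 fits that left out 1 library, the DNA damage call in 7, the cathepsin call in 6, the endothelial and decidual calls in 4 and the prolactin call in 3. The prolactin call held in 0 of 5 other settings (adjusted p = 0.16 with the Y-linked and 0.096 with the yolk sac covariate, 0.071 with quantile normalization and 0.093 without the filter on low values).

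Hdac8 loss without PKR was compared with the group labelled Hdac8 wild type without PKR, of which 2 libraries were low in Y-linked genes against the label. The claudin Cldn4 rose (1.41-fold, log2 0.49 ± 0.06 SE, adjusted p = 0.0058, n = 4 per group), as did the glycosyltransferase gene Galnt6 (0.4 ± 0.07), Fam241b (0.39 ± 0.06), Atp1a2 (0.37 ± 0.07) and Acp7 (0.34 ± 0.06). Islr2 (fold 0.646, -0.63 ± 0.08, adjusted p = 0.0064), Colec12 (-0.5 ± 0.08), Slit2 (-0.49 ± 0.09), Epha4 (-0.47 ± 0.08) and the prolactin-family gene Prl3c1 (-0.46 ± 0.05, adjusted p = 0.0029, uncertain) fell. In all, 26 genes passed, 15 higher and 11 lower. Erythroid genes were lower in 9 of 10 (median -0.18; Hbb-bh1 -0.54 ± 0.15 and Hba-x -0.52 ± 0.16, globins whose reads can be shared; limma called 0 over all genes and 4 adjusted over the list alone). For this list camera's adjusted p = 1.5e-05, and adjusted p = 0.3 with an estimated correlation. Cell cycle genes were lower in 26 of 29 (median -0.08, camera adjusted p = 0.00092), DNA damage response genes in 20 of 24 (median -0.04, adjusted p = 0.013) and imprinted genes in 19 of 27 (median -0.08, adjusted p = 0.033). Pregnancy-specific glycoproteins were higher in 18 of 22 (median 0.11, adjusted p = 0.0077), all 4 with an adjusted p = 0.86 with an estimated correlation. The erythroid and cell cycle calls held in 8 of 8 fits that left out 1 library, the DNA damage call in 6 and the imprinted and glycoprotein calls in 5. The glycoprotein call ended with the yolk sac mean as a covariate (adjusted p = 0.078). The yolk sac genes were at a median of -0.83 with 13 of 13 lower (camera adjusted p = 0.06). Without the libraries low in Y-linked genes limma called 0 genes (1287 at an unadjusted p under 0.05, 2 wild-type against 4 mutant libraries), and in a fit of these groups alone 8. With the Y-linked mean as a covariate it called 9, and with the yolk sac mean 40. The number was 12, 4 or 17 without wild-type replicate 2, 3 or 4 and 12, 7, 9 or 7 without mutant replicate 1, 2, 3 or 4.

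Genes called with PKR present were then followed into the PKR-null groups, which are separate placentas. In the Nipbl series, the 94 genes called higher had a median of 0.22 log2 with PKR present and 0.11 without, with 87 higher again (fry adjusted p = 0.00047). The 119 called lower had medians of -0.28 and -0.15, with 115 lower again (fry adjusted p = 5.6e-05). Of the Hdac8 series, the 88 called higher had medians of 0.23 and 0.16, with 88 higher again (fry adjusted p = 7.2e-06). The 69 called lower had medians of -0.23 and -0.13, with 68 lower again (fry adjusted p = 5.6e-05, over these 4 sets). Medians of genes chosen for passing a threshold are inflated in the comparison they were chosen in. The number called in both in the same direction was 5 in the Nipbl series and 19 in the Hdac8 series, against 0.14 for independent lists in each. Across genes, which are not independent replicates, r was 0.46 and 0.33. In the Nipbl series the median of genes called higher was 0.34 without wild-type replicate 2 with PKR, and that of genes called lower -0.09 without heterozygous replicate 1 with PKR. For Hdac8, the median of genes called lower was -0.25 without mutant replicate 4 with PKR. There r was 0.56 without that library and 0.11 without replicate 4 of the group labelled wild type without PKR. Of the 37 genes shared between the models, chosen for their sign with PKR present, 35 kept 1 sign in all 4 mutant comparisons. Between the models without PKR, r was 0.23 and rho 0.16 across genes. Islr2 and Colec12 were the 2 genes called in both there. Of the 19 genes called in the Nipbl series, 12 had the same sign in the Hdac8 series (median signed change 0.03 against 0.33), and of the 26 called there 22 had it in the Nipbl series. Leaving out Nipbl heterozygous PKR-null replicate 3 gave 14 genes called in both in place of 5. The number was 3 without wild-type replicate 2 or 3 and 2 without heterozygous replicate 1 or 2 of the groups with PKR. It was 2 without wild-type replicate 1, 2 or 3 and 3 without heterozygous replicate 1 or 2 of the PKR-null groups. In the Hdac8 series it was 9, 11 or 9 without wild-type replicate 1, 2 or 4 and 7, 11 or 10 without mutant replicate 1, 2 or 4 with PKR present. It was 10, 8, 3 or 9 without wild-type and 8, 6, 8 or 5 without mutant replicate 1, 2, 3 or 4 of the PKR-null groups.

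**Figure D4:**
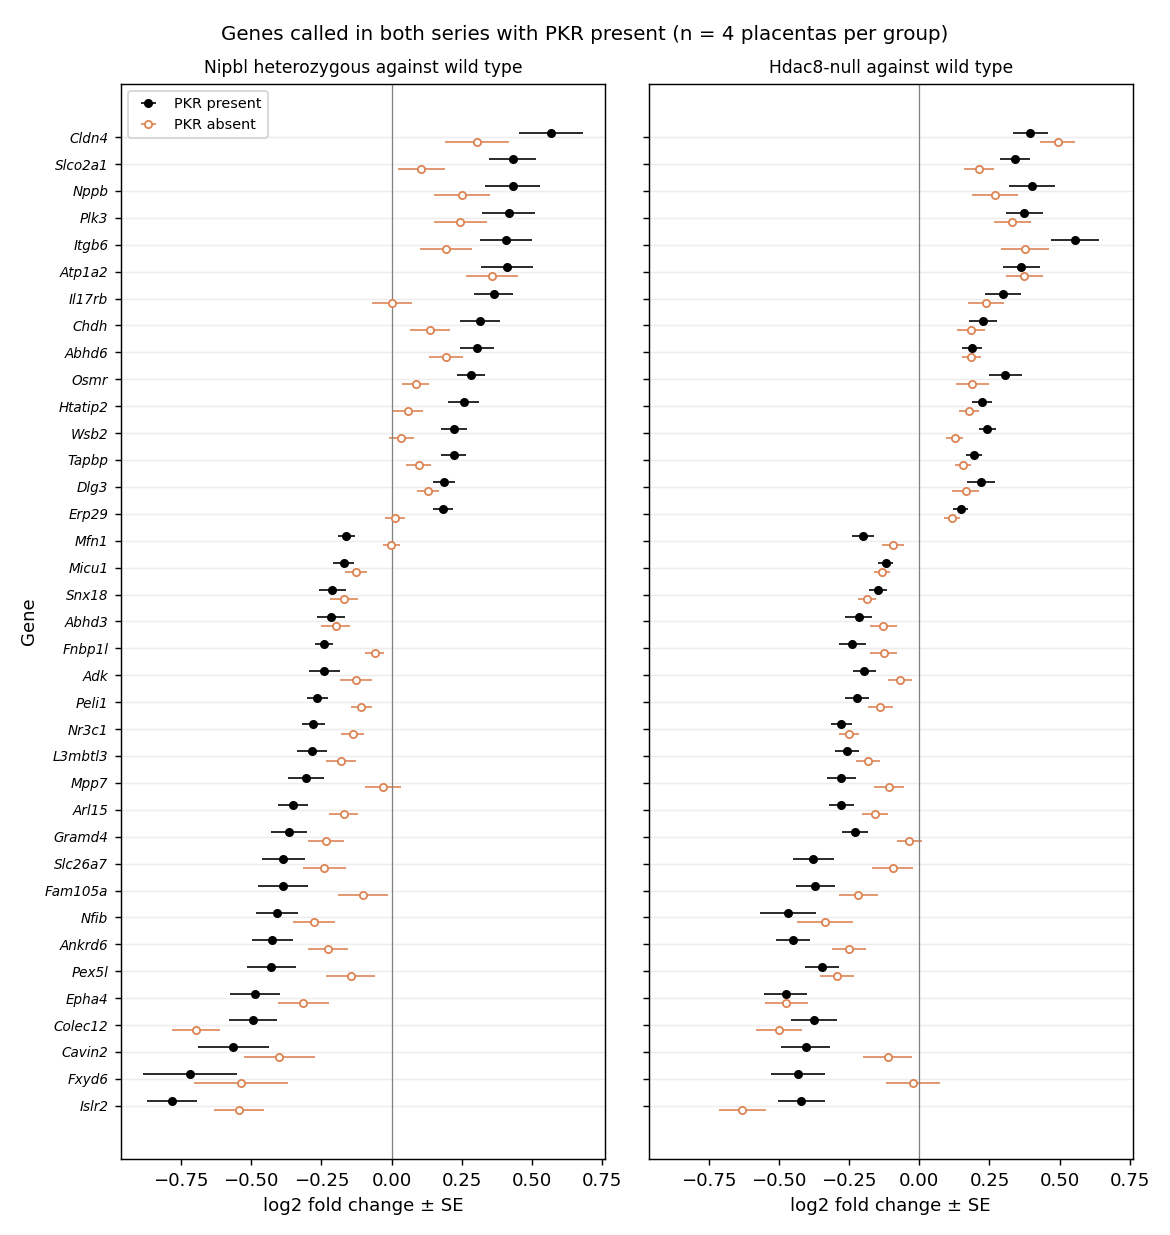
Log2 fold changes of the 37 genes called in both models with PKR present, in each of the 4 mutant comparisons. Of these, 35 have the same sign in all 4 comparisons.

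PKR loss in Nipbl heterozygotes asked which transcripts change with PKR in the mutant. Apart from Eif2ak2 (fold 0.62, log2 -0.69 ± 0.05 SE, adjusted p = 1.3e-05, n = 4 per group), the virus receptor and adhesion gene Cxadr rose (chromosome 16, 78301226 to 78359785; 1.27-fold, 0.34 ± 0.05, adjusted p = 0.034). So did Dcaf12l1 (chromosome X, 44786567 to 44790197; 1.23-fold, 0.3 ± 0.04, adjusted p = 0.012) and the membrane curvature protein gene Fnbp1l (chromosome 3, 122538719 to 122619714; 1.17-fold, 0.22 ± 0.03, adjusted p = 0.02). Gm6548, a transcribed pseudogene inside Eif2ak2 (chromosome 17, 78850504 to 78852544) outside the naming rule and uncertain because of the overlap, fell (-0.67 ± 0.09, adjusted p = 0.012). These 5 genes were all that passed. The number was 1, 8 or 17 without replicate 2, 3 or 4 of the heterozygotes with PKR and 1, 8 or 73 without replicate 1, 2 or 3 of those without PKR, and 1 in a fit of these groups alone.

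The heterozygous libraries with PKR also enter the comparison with wild type, with the opposite sign, so a list can lie in opposite directions in both through these libraries alone. Unfolded protein response genes were lower without PKR in 15 of 15 (median -0.17; Creld2 -0.36 ± 0.08, Sdf2l1 -0.3 ± 0.07; limma called 0 over all genes and 10 adjusted over the list alone). Here camera gave an adjusted p = 1.6e-09, against an adjusted p = 0.32 with an estimated correlation. Pregnancy-specific glycoproteins were lower in 22 of 22 (median -0.29; Psg18 -0.35 ± 0.1, Psg19 -0.28 ± 0.08, both uncertain; 0 and 5 in the same order). The camera test had an adjusted p = 3.8e-11, and an adjusted p = 0.25 with an estimated correlation. The prolactin family was lower in 19 of 21 (median -0.25), with an adjusted p = 1.7e-06 by camera and an adjusted p = 0.25 with an estimated correlation. Senescence and secretory factors were lower in 24 of 26 (median -0.17; Il1a -0.34 ± 0.11, Tnf -0.25 ± 0.08). Set against other genes by camera, the list had an adjusted p = 3.8e-06, and an adjusted p = 0.27 with an estimated correlation. NF-kB targets were lower in 15 of 17 (median -0.11, camera adjusted p = 0.004), interferon-stimulated genes in 26 of 33 (median -0.09, adjusted p = 0.004), spongiotrophoblast genes in 10 of 13 (median -0.06, adjusted p = 0.039) and yolk sac genes in 13 of 13 (median -0.54, adjusted p = 0.0049). In that order they had an adjusted p = 0.41, 0.76, 0.48 and 0.69 with an estimated correlation. Labyrinth syncytiotrophoblast genes, which build the exchange barrier, were higher in 12 of 16 (median 0.14; Gjb2 0.25 ± 0.06, Slc16a1 0.13 ± 0.04; 0 called over all genes and 2 adjusted over the list alone). Their camera adjusted p = 0.0012, the adjusted p = 0.058 with an estimated correlation and the fry adjusted p = 0.0053. Imprinted genes were higher in 24 of 27 (median 0.16; Plagl1 0.32 ± 0.08, Peg10 0.33 ± 0.1; camera adjusted p = 8.1e-06), nutrient transporters in 14 of 21 (median 0.05, adjusted p = 0.0049) and cohesin and its regulators in 12 of 15 (median 0.03, adjusted p = 0.037). They had an adjusted p = 0.25, 0.44 and 0.53 with an estimated correlation. Without heterozygous PKR-null replicate 3 the interferon list turned to the opposite direction (adjusted p = 0.49). Both groups held 3 libraries low in Y-linked genes. Of 8 fits that left out 1 library, 7 held the interferon, NF-kB and nutrient transporter calls, 6 the yolk sac and cohesin calls, 4 the spongiotrophoblast call and 8 the others. The spongiotrophoblast call ended with the yolk sac covariate (adjusted p = 0.076) and with quantile normalization (adjusted p = 0.2).

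PKR loss in Nipbl wild type called only Eif2ak2 (-0.66 ± 0.05, adjusted p = 2.4e-05, n = 4 per group) and Gm6548 (-0.67 ± 0.09, adjusted p = 0.018) of 14380 genes. With the smallest p-values after them, Sult6b2 (0.33 ± 0.06 log2, adjusted p = 0.28), Spn (0.43 ± 0.09, adjusted p = 0.47), Cct6b (0.4 ± 0.08, adjusted p = 0.47) and Ide (-0.44 ± 0.08, adjusted p = 0.33) did not pass. The number was 1 without replicate 1 or 2 of the group with PKR or replicate 1 or 3 of the PKR-null group. It was 4 without PKR-null replicate 2, 5 in a fit of these groups alone and 1 with the Y-linked mean as a covariate. Interferon-stimulated genes were lower in 30 of 33 (median -0.1), with an adjusted p = 5.2e-05 by camera and an adjusted p = 0.94 with an estimated correlation. The groups held 4 and 1 libraries low in Y-linked genes, and with the Y-linked mean as a covariate the adjusted p was 1. That covariate also ended the erythroid, cathepsin and yolk sac calls given next (adjusted p = 0.069, 0.13 and 0.83). DNA damage response genes (21 of 24 lower, median -0.06, camera adjusted p = 0.00077), yolk sac genes (12 of 13 lower, median -0.41, adjusted p = 0.025) and cell cycle genes (26 of 29 lower, median -0.07, adjusted p = 0.034) lay below other genes. Erythroid genes (9 of 10 higher, median 0.14, adjusted p = 0.023), nutrient transporters (17 of 21, median 0.05, adjusted p = 0.023), placental cathepsins (5 of 6, median 0.22, adjusted p = 0.034) and immediate early genes (12 of 17, median 0.05, adjusted p = 0.045) lay above them. All 7 had an adjusted p = 0.94 with an estimated correlation. The DNA damage call held in 8 of 8 fits that left out 1 library, the interferon call in 7, the nutrient transporter call in 6, the cathepsin call in 4, the erythroid, yolk sac and cell cycle calls in 3 and the immediate early call in 2. The immediate early call ended with the yolk sac covariate (adjusted p = 0.084). Without the filter on low values the cathepsin, cell cycle and immediate early calls ended (adjusted p = 0.74, 0.051 and 0.099), and with quantile normalization the cathepsin call (adjusted p = 0.2).

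PKR loss in the Hdac8 series called the same 4 genes in mutants and in the group labelled wild type, all on chromosome 17 within 0.17 Mb of Eif2ak2. Eif2ak2 fell (-0.58 ± 0.04 SE in mutants and -0.52 ± 0.04 in wild type, adjusted p = 2.9e-06 and 1.7e-05, n = 4 per group), as did Gm6548 (-0.76 ± 0.08 and -0.62 ± 0.08, adjusted p = 0.00028 and 0.0025, uncertain because it overlaps Eif2ak2). Strn, a scaffold of a phosphatase complex (78649898 to 78737322), fell by a similar amount in both (-0.27 ± 0.03 and -0.28 ± 0.03, adjusted p = 0.0014 and 0.0017), and Gpatch11 (78835516 to 78848308), the neighbour of Eif2ak2, rose (0.4 ± 0.05 and 0.36 ± 0.05, adjusted p = 0.00067 and 0.0025). Among the 94 tested genes within 10 Mb of Eif2ak2, 14.9% had an unadjusted p under 0.05 in mutants against 3.05% elsewhere (odds ratio 5.57, 95% interval 2.89 to 9.99, Fisher's exact p = 1.2e-06). The shares were 17% against 3.42% in wild type (odds ratio 5.78, 3.13 to 10.1, Fisher's exact p = 1.6e-07). In the Nipbl series they were 17% against 10.7% in heterozygotes (odds ratio 1.72, 0.934 to 2.98, Fisher's exact p = 0.063). They were 7.45% against 2.94% in wild type (odds ratio 2.66, 1.03 to 5.77, Fisher's exact p = 0.022). Genes side by side are not independent, so these tests describe the stretch. In wild type, 2 genes passed without the libraries low in Y-linked genes and 2 in a fit of these groups alone.

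**Figure D5:**
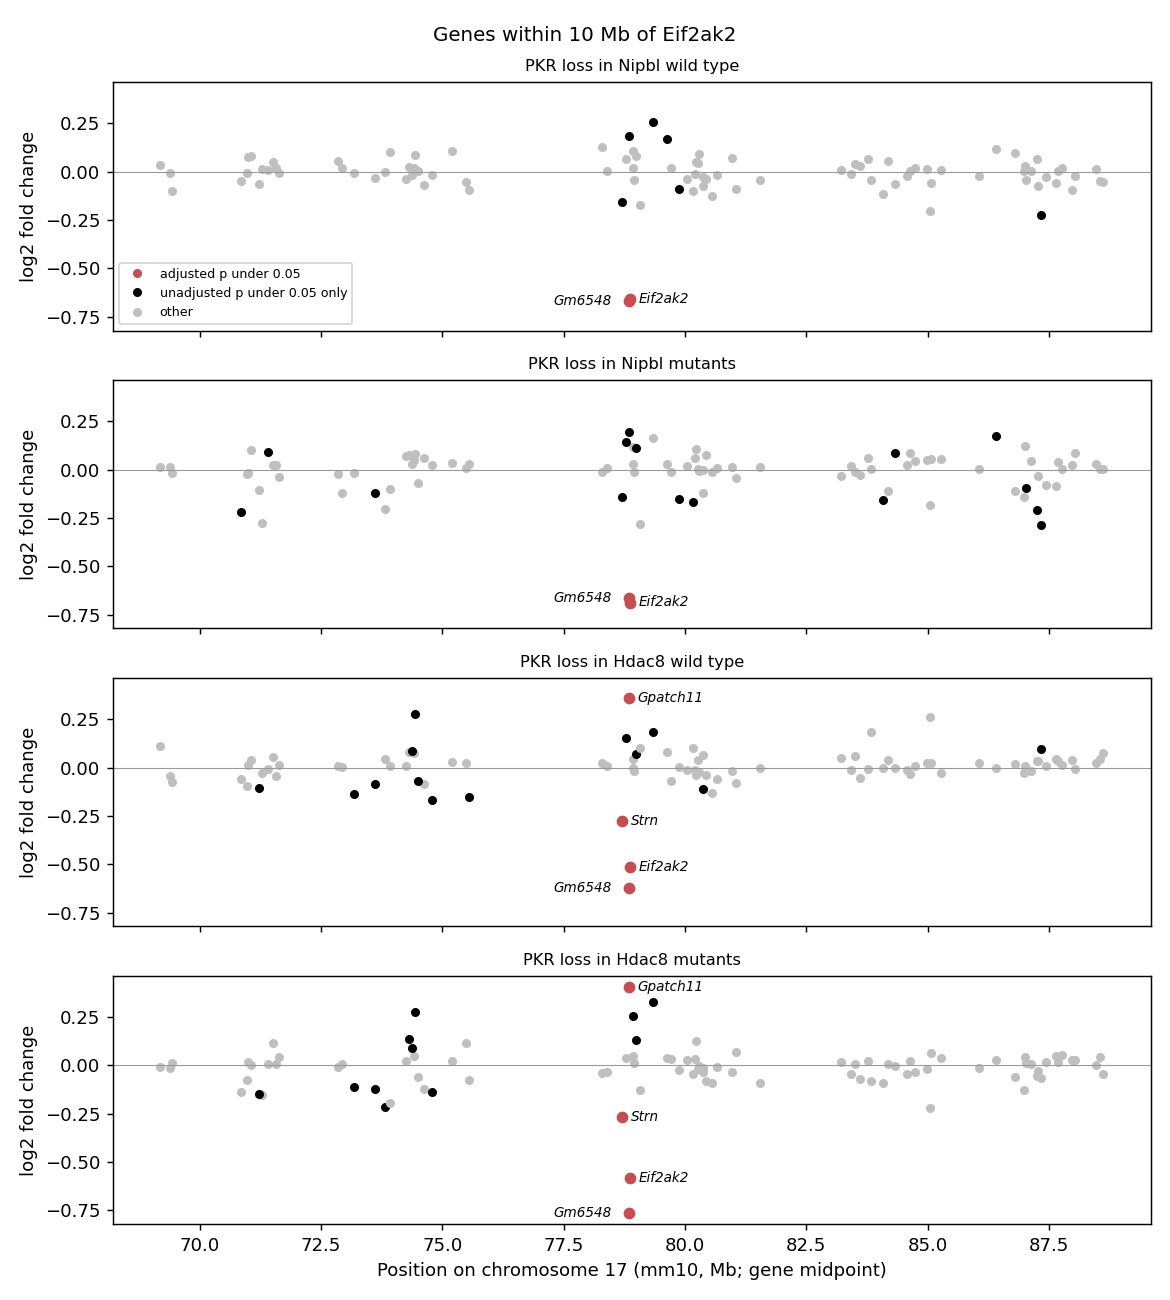
Log2 fold change with PKR loss of genes on chromosome 17 around Eif2ak2 by position in Mb (mm10), in Hdac8 mutant and wild-type placentas and in the Nipbl series. Eif2ak2 and Gm6548 lie below 0 in each comparison, and Gpatch11 lies at 0.4 and 0.36 and Strn at -0.27 and -0.28 in the Hdac8 series.

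Interferon-stimulated genes were higher in 33 of 33 in the group labelled Hdac8 wild type without PKR than in that with PKR (median 0.17; Ifi44 0.35 ± 0.07, Parp9 0.18 ± 0.04; limma called 0 over all genes and 11 adjusted over the list alone). For this list camera's adjusted p = 1.5e-29, and adjusted p = 0.096 with an estimated correlation. In the same comparison the yolk sac genes were higher in 13 of 13 (median 1.26; Alb 1.48 ± 1.01; camera adjusted p = 7.4e-06), and 2 of the 4 PKR-null libraries were low in Y-linked genes. Macrophage genes (10 of 13 higher, median 0.14, Adgre1 0.34 ± 0.09 and C1qa 0.39 ± 0.12, 0 called over all genes and 5 adjusted over the list alone, camera adjusted p = 4.8e-06) and erythroid genes (9 of 10, median 0.19, adjusted p = 1.6e-05) also lay above other genes. So did cell cycle genes (28 of 29, median 0.07, adjusted p = 8.2e-06) and senescence factors (17 of 26, median 0.05, adjusted p = 0.016). ATF4 and integrated stress response genes (18 of 23 lower, median -0.06, adjusted p = 0.001) and pregnancy-specific glycoproteins (21 of 22, median -0.07, adjusted p = 0.012) lay below, as did nutrient transporters (14 of 21, median -0.05, adjusted p = 0.02) and hypoxia response genes (17 of 22, median -0.04, adjusted p = 0.037). With an estimated correlation the adjusted p was 0.63 for yolk sac, cell cycle, senescence and nutrient transporter genes, 0.32 for macrophages and ATF4 genes, 0.22 for erythroid genes, 0.83 for pregnancy-specific glycoproteins and 0.74 for hypoxia. The interferon, yolk sac, macrophage and erythroid calls held in 8 of 8 fits that left out 1 library, the cell cycle and ATF4 calls in 7, the senescence and nutrient transporter calls in 5, the glycoprotein call in 4 and the hypoxia call in 3. The yolk sac covariate ended the senescence, glycoprotein, hypoxia and nutrient transporter calls (adjusted p = 0.26, 0.48, 0.26 and 0.26). The Y-linked covariate ended the senescence and nutrient transporter calls (adjusted p = 0.83 and 0.23), and quantile normalization the latter (adjusted p = 0.067). In Hdac8 mutants, 22 of 22 pregnancy-specific glycoproteins (median -0.11, camera adjusted p = 6.5e-05) and 12 of 15 unfolded protein response genes (median -0.07, adjusted p = 0.00028) were lower without PKR, and 25 of 33 interferon-stimulated genes were higher (median 0.05, adjusted p = 6.5e-05), all 3 with an adjusted p = 0.81 with an estimated correlation. The glycoprotein call held in 8 of 8 fits that left out 1 library and the others in 7. All 8 libraries compared in mutants were high in Y-linked genes, and the yolk sac list was at a median of 0.

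The interactions asked whether the mutant effect differs between PKR genotypes. In the Nipbl series limma called 0 of 14380 genes (732 at an unadjusted p under 0.05; n = 4 per group), and 1 without wild-type PKR-null replicate 2. The smallest p-values were those of Lrp3 (0.71 ± 0.15 log2), Dcaf12l1 (0.29 ± 0.06), Cxadr (0.36 ± 0.08), the neuropeptide precursor gene Vgf (-0.64 ± 0.12), Dad1 (-0.21 ± 0.05) and Micu2 (-0.19 ± 0.05), none of which passed (adjusted p = 0.69 to 0.84). Unfolded protein response genes were lower in 15 of 15, that is, their difference between heterozygous and wild-type placentas was smaller or opposite without PKR (median -0.17; Sdf2l1 -0.24 ± 0.1, Edem1 -0.15 ± 0.06). Here camera gave an adjusted p = 9e-07, against an adjusted p = 0.51 with an estimated correlation. Pregnancy-specific glycoproteins (20 of 22 lower, median -0.28, camera adjusted p = 9e-07), the prolactin family (19 of 21, median -0.26, adjusted p = 0.0013) and placental cathepsins (6 of 6, median -0.31, adjusted p = 0.0057) were also negative. So were senescence factors (19 of 26, median -0.13, adjusted p = 0.0042), immediate early genes (14 of 17, median -0.11, adjusted p = 0.0057) and NF-kB targets (11 of 17, median -0.06, adjusted p = 0.049). The first 4 had an adjusted p = 0.51 and the last pair an adjusted p = 0.6 with an estimated correlation. DNA damage response genes (23 of 24 positive, median 0.1, camera adjusted p = 0.0012), imprinted genes (23 of 27, median 0.11, adjusted p = 0.0042) and cell cycle genes (25 of 29, median 0.14, adjusted p = 0.005) were positive, as were labyrinth syncytiotrophoblast genes (13 of 16, median 0.14, adjusted p = 0.0085) and cohesin and its regulators (11 of 15, median 0.05, adjusted p = 0.019). In that order they had an adjusted p = 0.51, 0.51, 0.77, 0.22 and 0.51 with an estimated correlation. Without heterozygous PKR-null replicate 3 the cell cycle list turned negative (adjusted p = 0.41), and the NF-kB call held in 8 of 16 fits that left out 1 library, the others in 14 to 16. The labyrinth call ended with the Y-linked covariate (adjusted p = 0.091), and the prolactin and cathepsin calls with quantile normalization (adjusted p = 0.067 and 0.26). In the Hdac8 series limma called 0 of 14384 genes (338 at an unadjusted p under 0.05). The smallest p-values there were those of Cebpzos (0.26 ± 0.06), 1500015O10Rik (0.27 ± 0.06), Smim26 (0.27 ± 0.07), Katnal1 (-0.22 ± 0.04), Mmp9 (-0.29 ± 0.07) and Tm6sf2 (-0.19 ± 0.05), none of which passed (adjusted p = 1). There, with the label of the wild-type PKR-null group in doubt for 2 libraries, interferon-stimulated genes (30 of 33 negative, median -0.12, camera adjusted p = 2.2e-07), yolk sac genes (13 of 13, median -1.29, adjusted p = 0.00048) and unfolded protein response genes (12 of 15, median -0.07, adjusted p = 0.0019) were negative. All 3 came with an adjusted p = 0.89 with an estimated correlation.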

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

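Of the tests in this part, those of the sex mix in both models (in the Nipbl series on a covariate fixed beforehand), of reads shared with Eif2ak2, of r without its called neighbours and of a smaller change without PKR were chosen after the results they bear on had been seen, as were the fits with a yolk sac covariate or without selected libraries.

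In 10 of 174 groups of 4 libraries, 1 library lay far from the other 3, measured as its gap to the nearest of them divided by the range of the group. Chance alone gives about 1 in 20 such groups. Hdac8 in Nipbl heterozygotes without PKR had a ratio of 0.972 (7.3 against 6.82 to 6.83 log2), and Xist in the same group one of 0.877 (10.65 against 13.41 to 13.8). Eif2ak2 in Hdac8 wild type with PKR had a ratio of 0.981 (10.15 against 9.99). The yolk sac mean had a ratio of 0.835 in Hdac8 mutants with PKR (11.13 against 7.72 to 8.28) and of 0.836 in the group labelled Hdac8 wild type without PKR (7.58 against 9.84 to 10.28). Among genes named for their change, the ratio was 0.979 for Cavin2 in Nipbl heterozygotes with PKR (9.09 against 8.75), 0.884 for Suclg2 in Nipbl heterozygotes without PKR (9.35 against 9.43 to 9.44) and 0.909 for Cldn4 in Hdac8 mutants with PKR (10.8 against 10.48 to 10.51). It was 0.919 for Slit2 in Hdac8 wild type with PKR (7.95 against 7.53 to 7.57) and 0.847 for Acp7 in Hdac8 mutants without PKR (7.82 against 7.72 to 7.73). Nipbl was singled out because its mutant effect differed between the models (-0.43 log2, limma adjusted p = 0.00081), as it is the targeted gene in 1 of them.

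Attached yolk sac and the sex mix were weighed for the genes called for the mutant effect with PKR present. The values argue against the sex mix in the Hdac8 series and leave the other cases open. With the yolk sac mean as a covariate the median signed change of the called genes was 0.98 of its value in the Nipbl series, with 212 of 212 in the same direction, and 1 in the Hdac8 series. In the Nipbl series the median SE went from 0.055 to 0.062 and 1 of these genes was still called. Why the other calls ended was not tested. With the Y-linked mean as a covariate the ratio was 0.99 in the Nipbl series (158 of 212 called). In the Hdac8 comparison 0 of the 8 libraries were low in Y-linked genes, and Xist, which in male placentas comes from maternal cells, differed by -0.02 (exact permutation p = 0.89) and as a covariate left a ratio of 1. Litter and dissection, which the labels do not give, stay open beside an effect of the mutations, which is a hypothesis.

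Genes near Eif2ak2 on chromosome 17 differed with PKR loss in the Hdac8 series. Their log2 fold changes correlated at r = 0.51 between mutants and wild type over 93 genes, above 98.9% of 1000 random chromosome stretches (median 0.01, 95th percentile 0.33, highest 0.65). Without the called Gpatch11 and Strn r was 0.34, above 95.3%, and 55 of the 93 had the same sign in both, so part of it rests on these 2 genes. It is a value that DNA of another strain carried along with the PKR allele may give. Reads shared with Eif2ak2 are argued against for Gpatch11, which rose by at least 0.27 log2 at 2 SE below its estimate. Such reads may account for Gm6548, whose 2041 bases all lie inside Eif2ak2 and which fell with it in all 4 PKR loss comparisons. An effect of PKR loss itself on these neighbours was not tested and stays open. The strain of the flanking DNA is not given in the sources used here.

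Fewer genes were called for Nipbl heterozygosity without PKR (19) than with it (213). Without heterozygous PKR-null replicate 3, which lies far from its group, 0.786% of the genes tested were called (85 higher and 28 lower) in place of 0.132%, so this library may account for part of the gap. The sex mix cannot be told apart from it, since the Y-linked covariate gave 62 genes, more than the 19 without it but far fewer than with PKR present, and that library is also the 1 in its group high in Y-linked genes. A smaller change without PKR stays open too, since the 157 genes called in the Hdac8 series, signed by their change there, had a mean signed interaction of -0.118 log2 in the Nipbl series (137 negative, fry adjusted p = 0.011), and -0.105 (fry adjusted p = 0.028) without that library. With the Y-linked covariate it did not pass (-0.103, fry adjusted p = 0.054). The 212 genes chosen in the Nipbl series had -0.065 in the Hdac8 series (175 negative, fry adjusted p = 0.12; 0.04 without mutant replicate 3 with PKR and 0.033 without wild-type replicate 1 without PKR), which decides nothing there.

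Other splits of the same libraries into groups of the same size were drawn for each result. For genes called, the real split alone (1 of 35) is the smallest share possible and, unadjusted over tests, cannot exclude chance. Wide gaps argue against it in Nipbl heterozygotes (213 genes, highest other 40) and Hdac8 mutants (157, highest other 1) with PKR. Chance stays open in Nipbl heterozygotes without PKR (19, highest other 17). The split with 17 parts the 4 libraries low in Y-linked genes from the 4 others. The 19 became 2 without wild-type replicate 1 and 0 in a fit of these groups alone (limma, 1453 at an unadjusted p under 0.05). The splits decide nothing for PKR loss in Nipbl wild type (1 of 35; 2, highest other 0), in Hdac8 mutants (1 of 35; 4, highest other 0) or in Hdac8 wild type (2 of 35; 4, highest other 25). The genes called there are Eif2ak2 and its neighbours, whose change any mix of PKR genotypes removes. Chance cannot be excluded for PKR loss in Nipbl heterozygotes (5 of 35; 5, highest other 218) or for Hdac8 loss without PKR (2 of 35; 26, highest other 761). These high counts, and the 25 above, point to a structure of the samples. Nor can it be for the difference between models (14 of 100, 1 gene, highest other 5). The interactions' 0 genes (limma, 732 and 338 at an unadjusted p under 0.05) are reached by any split and decide nothing. The others reached 939, which points to such a structure, and 88.

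Chance cannot be excluded for any count of gene lists. In the Nipbl series as many lists were called in 2 of 35 splits for heterozygosity with PKR (11, highest other 13), 30 without it (8, 18), and 22 for PKR loss in heterozygotes (12, 20). They were 15 for PKR loss in wild type (8, 14) and 34 of 100 for the interaction (12, 19). For the Hdac8 series they were 8 of 35 for loss with PKR (12, 16), 26 without it (5, 17), and 35 for PKR loss in mutants (3, 13). They were 18 for PKR loss in wild type (10, 15), 96 of 100 for the interaction (3, 16) and 91 of 100 for the difference between models (2, 16). Chance cannot be excluded for the correlations either, where 1 of 35 is the smallest share possible. Splits with r as large between models were 1 of 35 for Nipbl libraries (0.46, highest other 0.4) and 2 for Hdac8 libraries (0.46, 0.49). With and without PKR they were 1 of 35 in the Nipbl series (0.46, highest other 0.42) and 9 in the Hdac8 series (0.33, 0.54).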

How the results depend on the processing

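Fits with a yolk sac covariate, with the Y-linked mean in the Hdac8 series or in list tests, and without selected libraries were chosen after the data were seen. No count or correlation of the comparisons reversed, and no named gene that passed turned under any setting run. Without Nipbl heterozygous PKR-null replicate 3, 2 list calls turned, interferon-stimulated genes for PKR loss in Nipbl heterozygotes and the cell cycle in the Nipbl by PKR interaction. The yolk sac list turned in some comparisons with its own mean as a covariate. Of the values of named called genes under other settings, 198 of 336 stayed past the threshold for Nipbl heterozygosity and 200 of 300 for Hdac8 loss with PKR present, and 85 of 165 and 85 of 160 with PKR absent. Where a value below moved, the cause was not tested. A pseudocount of 8 and quantile normalization kept every gene count within 1.5 times. DESeq2 and edgeR were not run, as whole reads could not be recovered. Depth is unknown, so its limits could not be assessed.

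In a fit of only the groups compared, the genes called numbered 324 for Nipbl heterozygosity with PKR present, 0 with PKR absent (limma, 1453 at an unadjusted p under 0.05), 1 for PKR loss in Nipbl heterozygotes and 5 in Nipbl wild type. They numbered 14 for Hdac8 loss with PKR present, 8 with PKR absent and 2 for PKR loss in Hdac8 wild type. Without the filter on low values Hdac8 loss with PKR present called 92. With the Y-linked covariate the numbers were 62 for Nipbl heterozygosity with PKR absent (0.431% of the genes tested, against 0.132% in the main result), 1 for PKR loss in Nipbl wild type, and 240 and 9 for Hdac8 loss with PKR present and absent. The yolk sac covariate gave 2 and 4 (0.0278%) for Nipbl heterozygosity with PKR present and absent and 40 for Hdac8 loss with PKR absent. Among Y-low libraries (no heterozygous replicate 1) Nipbl heterozygosity with PKR present called 19. Without the Y-low libraries of the group labelled Hdac8 wild type without PKR, Hdac8 loss with PKR absent called 0 (limma; 1287 at an unadjusted p under 0.05) and PKR loss in Hdac8 wild type 2.

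With the replicate number as a block, 3 genes (0.0209%) were called for Nipbl heterozygosity with PKR absent, 3 for PKR loss in Nipbl heterozygotes, and 44 and 10 for Hdac8 loss with PKR present and absent. No other count of genes moved by over 1.5 times. The block ended the endothelial and prolactin calls for Nipbl heterozygosity (adjusted p = 0.052 and 0.05) and the imprinted call for Hdac8 loss (adjusted p = 0.05), with PKR absent. The numbers do not pair the libraries: over 24 pairs with the same number per model, deviations from group means correlated at -0.59 to 0.59 in the Nipbl series and -0.71 to 0.56 in the Hdac8 series. In each model's 16 libraries, 5 and 7 correlated best with their own number, a hint from the data and not the design.

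For the gene lists, an estimated correlation left 0 calls in all 11 comparisons (limma's camera, 0 to 5 at an unadjusted p under 0.05). The yolk sac covariate left 6 for Nipbl heterozygosity with PKR present, 5 for PKR loss in Hdac8 wild type and 0 for the difference between models (1 at an unadjusted p under 0.05). With the Y-linked covariate 15 were called for Nipbl heterozygosity and 14 for Hdac8 loss with PKR absent and 5 for the Hdac8 by PKR interaction. No filter gave 5 for PKR loss in Nipbl wild type, and quantile normalization 5 for PKR loss in Hdac8 mutants, 6 for the Hdac8 by PKR interaction and 1 for the difference between models.

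With 1 library left out, the genes called ranged from 13 to 269 for Nipbl heterozygosity with PKR present, 0.0139% to 0.786% of the genes tested with PKR absent (2 genes to 85 higher and 28 lower), 1 to 73 for PKR loss in Nipbl heterozygotes, 1 to 4 in Nipbl wild type and 0 to 1 for the Nipbl by PKR interaction. They ranged from 21 to 224 for Hdac8 loss with PKR present, 4 to 20 with PKR absent, 4 to 5 for PKR loss in Hdac8 mutants, 4 to 4 in Hdac8 wild type, 0 to 0 for the interaction and 1 to 2 for the difference between models. The lists called ranged, in the same order, from 7 to 13, 5 to 12, 10 to 19, 2 to 10, 8 to 18, 4 to 15, 3 to 10, 3 to 8, 5 to 12, 1 to 9 and 1 to 4. The correlation between models ranged from 0.34 to 0.61 with 5 to 44 genes called in both. Between PKR genotypes it ranged from 0.36 to 0.5 in the Nipbl series, with 2 to 14 genes called in both and medians of 0.08 to 0.34 for genes called higher and -0.17 to -0.09 for genes called lower. It ranged from 0.11 to 0.56 in the Hdac8 series, with 3 to 20, 0.15 to 0.21 and -0.25 to -0.12. The targeted genes ranged from -0.53 to -0.49 and -0.43 to -0.38 for Nipbl with PKR present and absent, -0.35 to -0.23 and -0.53 to -0.4 for Hdac8. Eif2ak2 ranged from -0.72 to -0.63 in Nipbl heterozygotes, -0.68 to -0.63 in Nipbl wild type, -0.61 to -0.56 in Hdac8 mutants and -0.54 to -0.48 in Hdac8 wild type.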

Other observations

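The comparison of the 157 genes called in the Hdac8 series with the Nipbl series, and the reverse, was chosen after the mutant effects had been seen. The choice of genes in 1 model and the test in the other keeps the values free of selection.

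Further genes among the 37 called in both models with PKR present were chosen after their values were seen. The prostaglandin transporter gene Slco2a1 rose in both (0.43 ± 0.08 SE in Nipbl heterozygotes and 0.34 ± 0.05 in Hdac8 mutants, limma adjusted p = 0.025 and 0.0086), as did the interleukin receptor gene Il17rb (0.36 ± 0.07 and 0.3 ± 0.06). Fnbp1l, which was higher with PKR loss in Nipbl heterozygotes, was lower in both mutants with PKR present (-0.24 ± 0.03 and -0.24 ± 0.05), where the Nipbl values share the heterozygous libraries with PKR.

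Genes called in the Hdac8 series had a mean signed change of 0.214 log2 in Nipbl heterozygotes with PKR and 0.096 without it, a ratio of 0.45. Of the 157, 153 and 127 moved in the direction of their Hdac8 change. The 212 genes called in the Nipbl series had 0.179 in Hdac8 mutants with PKR and 0.114 without, a ratio of 0.64, with 203 and 196 in the same direction. The hypothesis that the shared change may be smaller without PKR was tested as the mean signed interaction, adjusted over both series. It was -0.118 in the Nipbl series (fry adjusted p = 0.011, and 0.00036 to 0.028 with 1 library left out). With the Y-linked covariate it was -0.103 (fry adjusted p = 0.054), which did not pass, and with the yolk sac covariate -0.12 (fry adjusted p = 0.0098). In the Hdac8 series it was -0.065 (fry adjusted p = 0.12, and 0.033 to 0.23 with 1 library left out). No single gene passed the interaction test in either series (limma called 0, with 732 and 338 at an unadjusted p under 0.05). The PKR-null groups share no libraries with the groups with PKR, so litter or batch stays open.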
